A study of Mus musculus with 17 samples.

How the data were processed

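The data were deposited peak lists from 11 ChIP-seq libraries (3 for Sirt6 and 8 for H3K9ac and H3K56ac) and 1 table of CMS-IP windows that held 4 libraries, an IP and an input for KO and for WT. The whole-cell extract libraries entered only as the control of the Sirt6 peak calls. Groups were taken from the sample labels, with 1 library in each of the 17 groups. Mouse embryonic stem cells were grown on feeder cells that were removed by plating, per the labels' protocols. RA was used from a 0.01 M stock at a 10000-fold dilution for 2 days, per the labels' protocols. For the 2 KO Sirt6 libraries the labels give antibody amounts of 1 and 5 in units that differ between fields, so only lower and higher amounts are distinguished.

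Reads were aligned with BWA 0.5.9 to mouse build mm9 and peaks were called with MACS2 2.0.10, per the submitters' processing notes, which also name Picard; its step is not given in the sources used here. Peaks were called per library at a q limit of 0.01, per the file headers. The Sirt6 lists were called against whole-cell extract, and the 8 acetylation lists were called with no control library, per the file headers. Reads that pile up in any library are therefore not removed from the acetylation lists. The estimated fragment length differed between acetylation libraries, per the file headers. It was shortest in the untreated WT libraries, at 155 bp for H3K9ac and 175 bp for H3K56ac, and was 198 to 227 bp in the others. The median peak length was 186 and 212 bp in the untreated WT lists, and 244 to 281 bp in the others. The deposited lists give for each peak the pileup signal at its summit, a −log10 p and −log10 q, and a fold enrichment over the local background, all computed by the authors with MACS2. Total tags before filtering ranged from 2196741 for the WT Sirt6 library to 50412452 for the KO Sirt6 library with more antibody, per the file headers.

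For CMS-IP, the authors' table gives read counts and RPKM for each of the 4 libraries, and edgeR's log2 fold change, log2 abundance, p-value and adjusted p, per the column names; edgeR and mm9 are named in the submitters' processing notes. The aligner for these libraries is not given in the sources used here. The deposited p-values all lay under 0.001, and the table repeats its header once, between the windows lower and those higher in KO. The library sizes implied by the deposited counts and RPKM were 11413874 reads for KO IP, 13451714 for WT IP, 23924232 for KO input and 16623305 for WT input. The authors' p-values lay close to those of a binomial test on the IP reads alone, with a median difference of 0.0214 on the log10 scale, so they carry no replicate variation and make no use of the input. There were 0 columns of per-sample values left unused.

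From the lists, regions were formed by merging peaks of 2 lists that overlapped by 1 bp or more, and each region was called in both, in the first only or in the second only. Shares carry Wilson 95% intervals, differences of shares Newcombe intervals, and ratios of counts exact (Clopper-Pearson) intervals; all cover counting error only. Expected overlap was described by 1000 random placements of the intervals on their own chromosomes, which do not follow mappability or open chromatin, and no p-value was taken from them. A share of 0 was given the limit that 3 counts allow. Ratios of CMS-IP and input reads were computed from summed counts scaled to the library sizes. The steps were tested on simulated data: for lists of 2789 and 3593 peaks, 900 of 900 planted shared regions were recovered, and 483 of 500 ratio intervals held the true value. The planted peaks had equal lengths and nearly equal positions, so their recovery checks the merging alone and says nothing of missed peak calls. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.

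Before the data were examined, the comparisons, the alternatives and the rule for named regions were fixed: the 5 regions with the highest fold enrichment per class, the 10 highest Sirt6 peaks, and the 5 CMS-IP windows with the smallest p per direction, of which the text names some. The part of the rule that takes members of gene lists was not applied, for want of gene positions. The fold of a shared region is that of the KO list, or of the RA list in comparisons between conditions. The alternatives were a −log10 q of at least 10, overlap of 50% of the shorter peak, lists of equal length, peaks joined within 1000 bp, autosomes only, and a distance of 1000 bp in place of overlap. For CMS-IP they were an adjusted p under 0.01, joined windows and autosomes only. Added after seeing the data were lists of equal length for the Sirt6 shares, all alternatives for the Sirt6 shares in RA against untreated, the mean KO minus WT difference in Sirt6 share within mark and condition, leaving out regions called in all 8 acetylation lists, Benjamini-Hochberg adjustment over all windows tested, leaving out chromosomes 1 and 14, and an exact test of IP against input reads in each window. That test compares the 4 libraries only. Its null odds ratio was 0.590, the value the library sizes give. A null of 1 would call windows lower in KO from library size alone. On 3780 simulated windows with no difference it called 1, against 83 with a null of 1. The simulated windows were not selected, whereas the listed windows were selected on the IP reads that the test uses. That rate of false calls therefore does not carry over to the listed windows. In simulated windows it called 58.9% of IP signals raised 5 times and 30.9% of those lowered 5 times. Only the KO IP was changed there, so raised windows held more IP reads than lowered ones. These shares therefore do not separate a bias of the test toward gains from the number of reads. The planned positions relative to genes and the planned gene lists need an annotation in mm9 and were not analysed here, and no coordinates were converted between builds.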

Results

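The series profiled mouse embryonic stem cells that carried Sirt6 (WT) or lacked it (KO). Sirt6 is a NAD-dependent histone deacetylase that acts on acetylated lysines 9 and 56 of histone H3 (H3K9ac and H3K56ac). Chromatin immunoprecipitation with sequencing (ChIP-seq) was run for both marks in untreated cells and in cells exposed to retinoic acid (RA), a differentiating agent, for 2 days and harvested a day after its removal. Sirt6 itself was profiled in untreated cells only, with 1 WT library and 2 KO libraries that differed in antibody amount. A separate CMS-IP experiment, which enriches bisulfite-treated DNA carrying 5-hydroxymethylcytosine, compared untreated KO and WT cells and had an input library for each. The 17 samples formed 17 groups of 1 library, so no difference below has a replicate check and no test between conditions is reported. Intervals are 95% intervals that cover counting error only, and regions or windows are not replicates. The acetylation libraries held 5782181 to 10250030 tags after filtering. All positions are in mouse build mm9. No annotation of that build was used here, so regions are named by position and the genes at them were not analysed.

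The first question was whether the Sirt6 antibody gave peaks that depended on Sirt6. The WT library gave 14510 peaks and both KO libraries gave 0. The KO libraries were the deeper ones: the WT library held 2008232 tags after filtering, against 40006795 for the KO library with less antibody and 48956556 for the one with more. WT peaks had a median length of 384 bp and a median fold enrichment of 8.08, the authors' own value per peak. The peak with the highest fold enrichment, 33.3, lay on chromosome 14 from 120876947 to 120877540. It was followed by peaks on chromosome 8 from 19784501 to 19785638 (29.7), on chromosome 2 from 47497985 to 47498331 (28.9), on chromosome 8 from 125091873 to 125092872 (28.8) and on chromosome 1 from 33464838 to 33465239 (28.3). The other peaks among the 10 highest lay on chromosome 14 from 119337177 to 119337909, from 99444244 to 99445328 and from 121777441 to 121778388, and on chromosome 8 from 20019314 to 20020424 and from 114167371 to 114167798. Of the 10 highest, only the peaks on chromosomes 2 and 1 overlapped regions called in all 8 acetylation lists. The KO lists were called against another whole-cell extract library than the WT list, with 5113859 control tags for KO and 6251712 for WT. With the stricter limit of 10 on the authors' −log10 q, 6438 WT peaks were left.

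In untreated cells, regions with an H3K9ac peak in KO but not in WT were often sites of Sirt6 peaks in WT cells. There were 2050 H3K9ac regions called only in KO, 1539 called in both genotypes and 1230 called only in WT. A WT Sirt6 peak overlapped 58.7% of the KO-only regions (1203 regions; Wilson interval 56.5% to 60.8%), 9.29% of the regions called in both (7.94% to 10.8%; 1.48% without the regions called in all 8 acetylation lists) and 0.732% of the WT-only regions (9 regions; 0.385% to 1.38%). The difference between KO-only and WT-only regions was 58.0 percentage points (Newcombe interval 55.7 to 60.1). Of the 5 KO-only regions with the highest fold enrichment, 4 overlapped a Sirt6 peak. They lay on chromosome 6 from 15554185 to 15554561 (30.6), on chromosome 8 from 15442519 to 15442923 (30.5) and from 42533761 to 42534149 (30.3), and on chromosome 3 from 113595516 to 113595884 (30.4). The remaining one, on chromosome 18 from 31453501 to 31453828 (28.8), did not. Of these 5 regions, 4 were also among the 5 highest that WT cells gained in their H3K9ac list after RA; the one on chromosome 8 from 15442519 was not. The 5 highest WT-only regions held no Sirt6 peak, and the first of them lay on chromosome 13 from 45896151 to 45896354 (27.4). The 5 highest regions called in both genotypes, led by chromosome 13 from 86453014 to 86453370 (38.5), all overlapped Sirt6 peaks and were called in all 8 acetylation lists. The ratio of KO-only to WT-only regions, 1.67 (1.55 to 1.79), turned to 0.615 with the stricter q limit. The difference in Sirt6 overlap fell to 21.8 percentage points at that limit.

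H3K56ac in untreated cells showed the same direction at Sirt6 peaks, although fewer regions were called in KO. There were 859 KO-only, 1369 shared and 1370 WT-only regions, a ratio of KO-only to WT-only regions of 0.627 (0.575 to 0.683). The KO library held 0.742 of the filtered tags of the WT library. Sirt6 peaks overlapped 42.8% of the KO-only regions (39.6% to 46.2%), 16.0% of the shared regions (14.2% to 18.03%; 22.3% without those called in all 8 lists) and 7.37% of the WT-only regions (6.10% to 8.88%). The difference between KO-only and WT-only regions was 35.5 percentage points (31.9 to 39.0), and it was 10.1 with the stricter q limit. At that limit the KO-only share was 11.1% (8.40% to 14.6%) and no longer above the shared regions' 13.6% (11.8% to 15.8%). The KO-only region with the highest fold enrichment lay on chromosome 16 from 71414606 to 71414957 (28.3) and held no Sirt6 peak. The next, on chromosome 15 from 62601911 to 62602224 (26.8), overlapped one. The region on chromosome 16 was also among the 5 highest that WT cells gained in their H3K56ac list after RA. So were other high KO-only regions, on chromosome 4 from 11994550 and on chromosome 5 from 108011724. The highest WT-only region lay on chromosome 15 from 91432120 to 91432351 (30.4). The highest shared regions lay on chromosome 12 from 50352091 to 50352463 (36.6) and on chromosome X from 60379570 to 60379977 (36.5). Of the 859 KO-only H3K56ac regions, 394 overlapped a KO-only H3K9ac region.

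After RA the lists of the 2 genotypes shared more regions, and KO-only regions were no longer concentrated at Sirt6 peaks to the same degree. For H3K9ac, 2282 regions were shared, 859 were KO-only and 331 were WT-only. Sirt6 peaks of untreated WT cells overlapped 11.3% of the KO-only regions (9.35% to 13.6%), 7.84% of the shared regions (3.42% without those called in all 8 lists) and 1.51% of the WT-only regions (0.647% to 3.49%), a difference between KO-only and WT-only of 9.78 percentage points (7.01 to 12.2). That difference was 2.65 with the stricter q limit and 3.19 with lists of equal length, and the KO-only share then lay below that of the shared regions (3.55% against 7.02%, and 5.15% against 8.12%). For H3K56ac, 1646 regions were shared, 591 were KO-only and 405 were WT-only. Their Sirt6 overlap was 11.5%, 13.2% (10.7% to 16.2%) and 15.6% (12.4% to 19.4%), and the difference of -2.36 percentage points had an interval that held 0 (-6.95 to 2.01). It was 4.42 (1.51 to 7.44) with the stricter q limit and -8.25 (-12.5 to -4.03) with lists of equal length, so its sign depends on the choice of peaks. The highest KO-only regions were on chromosome 3 from 14983581 to 14983918 (17.3) for H3K9ac and on chromosome 15 from 62601918 to 62602215 (23.7) for H3K56ac, and both overlapped a Sirt6 peak. Of the other 4 among the 5 highest, 3 held no Sirt6 peak for H3K9ac and none held one for H3K56ac. Whether RA changed the genotype difference was not tested, since each group held 1 library, and no Sirt6 library from RA-treated cells was used here.

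**Figure D1:**
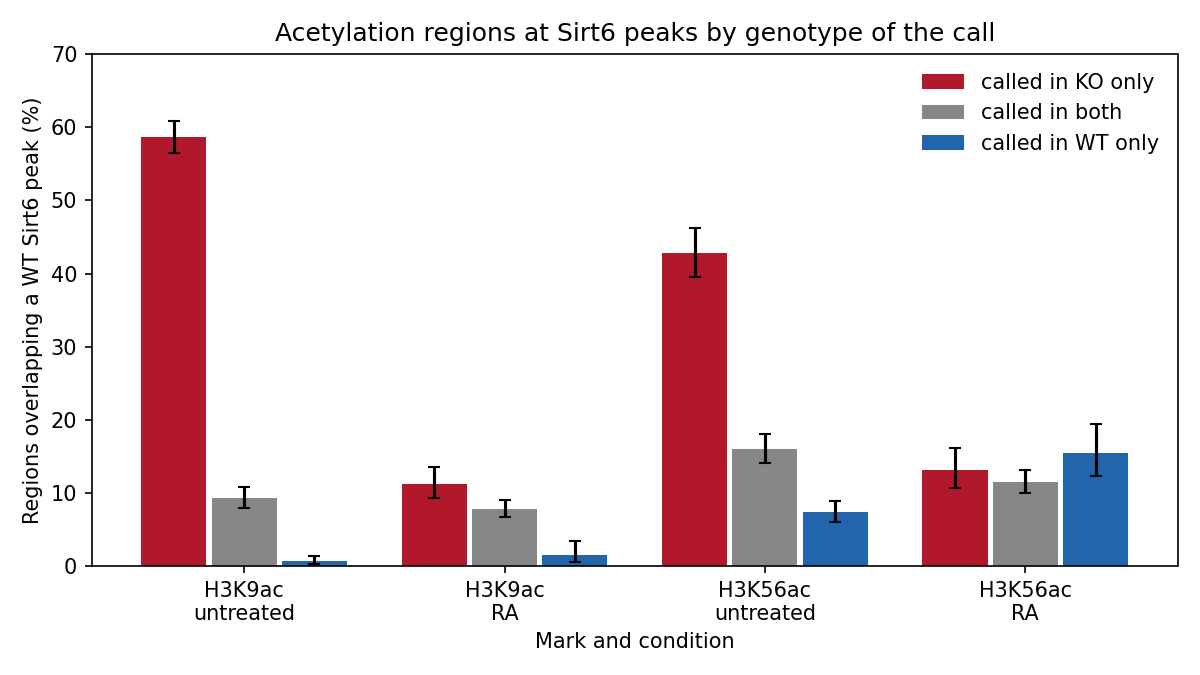
The bars give the percent of acetylation regions that overlap a Sirt6 peak of untreated WT cells, for regions called in KO only, in both genotypes and in WT only, per mark and condition; error bars are 95% Wilson intervals. The KO-only bars in untreated cells stand at 58.7% for H3K9ac and 42.8% for H3K56ac, and the other bars lie at or below 16.0%.

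Compared within a genotype, the KO regions called only in untreated cells lay at Sirt6 peaks far more often than those called only after RA. Of the H3K9ac regions in KO, 1573 were called only in untreated cells, 2013 in both conditions and 1129 only after RA. Sirt6 peaks overlapped 71.3% of the untreated-only regions (69.0% to 73.5%) and 4.61% of the RA-only regions (3.53% to 5.99%). For H3K56ac in KO the corresponding numbers were 656, 1573 and 662 regions, with Sirt6 overlap of 55.6% (51.8% to 59.4%) in untreated-only and 6.95% (5.25% to 9.14%) in RA-only regions. In WT cells the H3K9ac lists had 953 untreated-only and 802 RA-only regions, with Sirt6 overlap of 0.734% and 4.86%. WT H3K56ac had 1161 untreated-only and 476 RA-only regions, with Sirt6 overlap of 11.5% and 14.1%, a difference of 2.53 percentage points (-0.918 to 6.35) that was 10.6 (7.71 to 13.6) with lists of equal length. The highest untreated-only H3K9ac regions in KO lay on chromosome X from 21961844 to 21962165 (25.2) and on chromosome 12 from 53264892 to 53265124 (19.6), and both overlapped Sirt6 peaks. Of the 1203 untreated KO-only H3K9ac regions at Sirt6 peaks, 82 were also called in KO after RA, or 6.82% (5.53% to 8.38%), against 457 of the 847 that were not at Sirt6 peaks, or 54.0% (50.6% to 57.3%). WT cells after RA had calls at 3.08% (2.24% to 4.21%) and 42.4% (39.1% to 45.7%) of these regions. Strength of the calls was not held equal between these sets. Of the untreated KO-only H3K9ac regions, 1203 of 2050 lay at Sirt6 peaks, but 148 of 677 with the stricter q limit on the acetylation and Sirt6 lists. The contrast therefore cannot be read as an effect of RA at Sirt6 peaks. With the stricter q limit the untreated-only share in KO was 34.8% (29.6% to 40.5%) for H3K9ac and 11.9% (8.30% to 16.8%) for H3K56ac, the latter no higher than the 13.1% of regions called in both conditions; in WT H3K56ac it was 2.53%. The ratio of RA-only to untreated-only regions reversed with the stricter q limit for H3K9ac in both genotypes, from 0.718 to 3.34 in KO and from 0.842 to 1.06 in WT, where the interval (0.960 to 1.18) held 1.

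Seen from the Sirt6 list, 9.30% of the 14510 WT Sirt6 peaks (8.84% to 9.78%) were overlapped by an untreated KO H3K9ac peak and 1.03% (0.882% to 1.21%) by an untreated WT H3K9ac peak. Without the regions called in all 8 lists these shares were 8.37% and 0.110%, so most of the WT overlap lay at regions that every acetylation list held. For untreated H3K56ac the shares were 4.03% (3.72% to 4.36%) in KO and 2.20% (1.97% to 2.45%) in WT. After RA they lay between 1.25% and 1.89% in the 4 lists. The highest share over 1000 random placements of the Sirt6 peaks on their own chromosomes was 0.186%, for the KO untreated H3K9ac list. Of the 3628 Sirt6 peaks with the highest fold enrichment, 19.3% (18.1% to 20.6%) overlapped an untreated KO H3K9ac peak, against 4.66% (4.02% to 5.39%) of the 3628 with the lowest. The order was the opposite for WT H3K9ac, untreated (0.992% against 2.40%) and after RA (1.41% against 2.62%), and both shares were 2.87% for KO H3K9ac after RA. For untreated H3K56ac they were 7.99% against 3.42% in KO and 4.16% against 2.73% in WT. The share of WT Sirt6 peaks reached by KO H3K9ac fell to 4.02% with the stricter q limit on both lists, where that of WT H3K9ac was 1.77%. For untreated H3K56ac the gap between KO and WT narrowed too at that limit.

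The last comparison asked where 5-hydroxymethylcytosine differed between KO and WT cells. The authors' deposited table listed 3780 windows of 500 bp with p under 0.001, of which 2218 were higher and 1562 lower in KO. That split depends on the criterion: 42 were higher and 44 lower at an adjusted p under 0.01 in the authors' deposited table, and 484 higher and 34 lower in an exact test of IP against input reads. How far that test favours gains was not settled, since simulated gains held more IP reads than simulated losses. The windows were listed for their IP difference, so IP ratios summed over them describe that selection and do not estimate an effect. The exact test used the same IP reads, so its calls carry that selection too. In the higher windows the KO IP library held 2.65 times the reads of the WT library, scaled to library size (exact interval 2.62 to 2.68) and the input libraries were level, with a KO to WT ratio of 1.00 (0.990 to 1.01). In the lower windows the IP ratio was 0.384 (0.378 to 0.389) and the KO input was lower too, with a ratio of 0.547 (0.539 to 0.556). The lower windows were concentrated on chromosome 14, with 519 windows, and chromosome 1, with 323 windows. On chromosome 14, 236 windows lay between 100006501 and 109311500, where the ratio was 0.363 in the IP and 0.393 in the input. The higher windows were most numerous on chromosomes 6 (335 windows), 11 (265 windows) and 10 (216 windows). Without chromosomes 1 and 14, a choice made after seeing the data, 2130 windows were higher and 720 lower, and the input ratio in those lower windows was still 0.634 (0.620 to 0.649).

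The lower window with the smallest p in the authors' deposited table lay on chromosome 14 from 106505501 to 106506000, with a log2 fold change of -1.69 and an adjusted p of 5.17e-29. It held 121 IP reads in KO and 465 in WT, and 29 and 80 input reads. The authors' deposited table gave the next lower windows on chromosome 3 from 8510001 to 8510500 (log2 fold change -6.51), chromosome 1 from 63246501 to 63247000 (-9.11), chromosome 17 from 39984501 to 39985000 (-1.38) and chromosome 10 from 81088501 to 81089000 (-9.09). The KO IP library held 0 reads in the windows on chromosomes 1 and 10, so their fitted fold changes are no measure of size. In the window on chromosome 10 the KO input held 0 reads too, against 18 in WT. The higher windows led, in the authors' deposited table, with chromosome 11 from 6313001 to 6313500 (log2 fold change 9.42, adjusted p 1.50e-18), where the WT IP held 0 reads and the KO IP 78, and where the WT input also held 0 reads, against 12 in KO. The authors' deposited table then listed chromosome 11 from 5803001 to 5803500 (2.73), from 5802501 to 5803000 (3.09) and from 5847001 to 5847500 (2.61), and chromosome 7 from 29997501 to 29998000 (1.92). In the window on chromosome 7 the KO input was higher too, with an RPKM of 2.84 against 0.963 in WT, beside 21.2 and 5.65 in the IP. In those on chromosome 11 the KO and WT input RPKM were 3.26 and 3.25, 4.10 and 3.61, and 3.43 and 2.29, in that order. They lay in a stretch of higher windows with an input ratio of 1.57. These p-values compare 1 KO library with 1 WT library and not the conditions. The adjusted p was the p multiplied by 3084167 windows, of which chance alone would put at most about 3084 under 0.001. An adjusted p under 0.1 was given to 139 windows of the authors' deposited table, 74 higher and 65 lower.

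**Figure D2:**
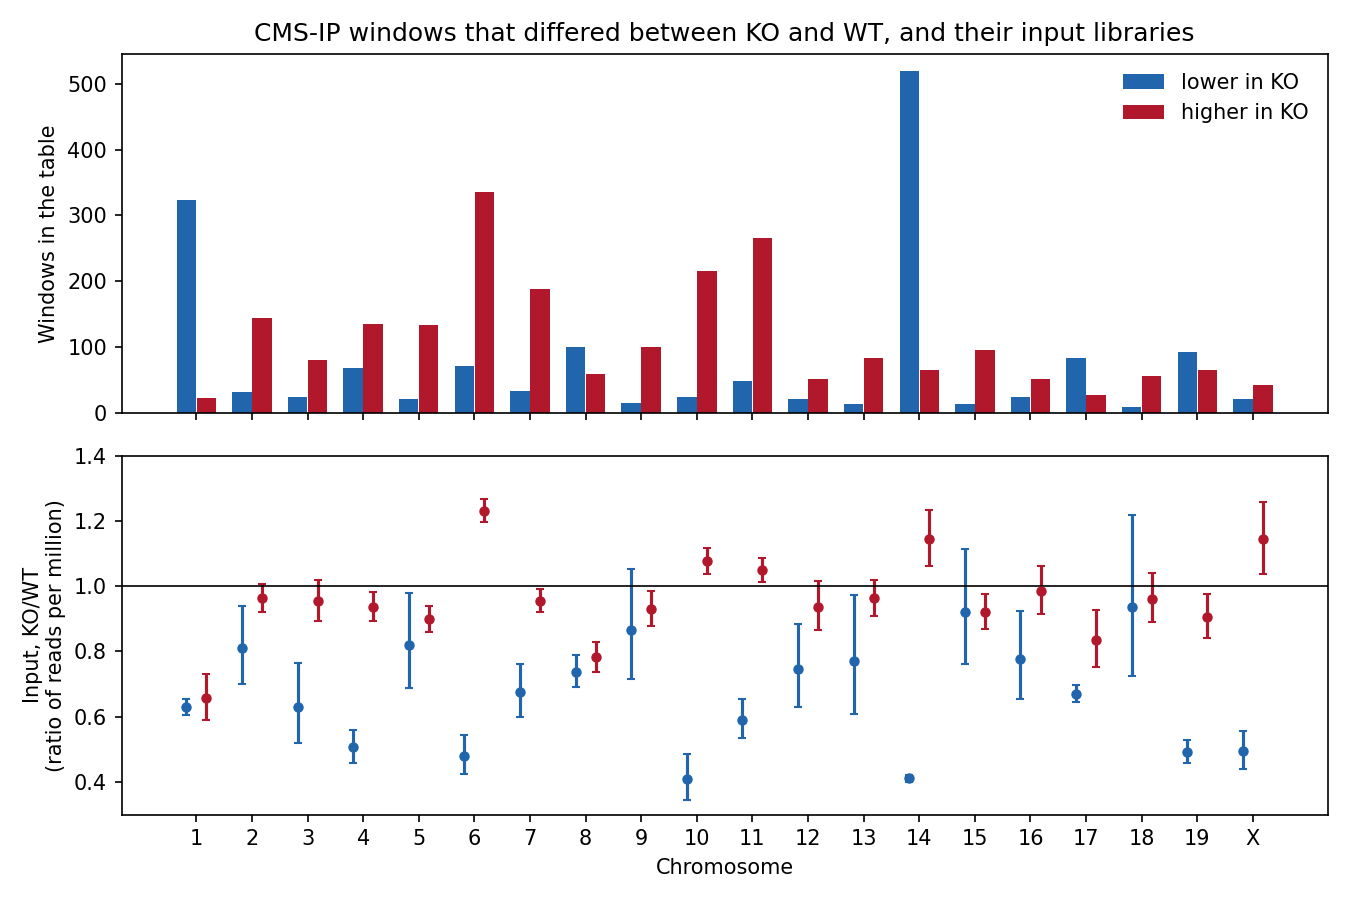
The upper panel counts the windows lower and higher in KO per chromosome in the authors' deposited table, and the lower panel gives the KO to WT ratio of input reads scaled to library size and summed over the same windows with exact 95% intervals. Windows lower in KO peak on chromosome 14 (519 windows), where their input ratio is 0.411.

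Few of these windows touched a ChIP-seq peak. Sirt6 peaks overlapped 59 of the higher windows, or 2.66% (2.07% to 3.42%), and 29 of the lower windows, or 1.86% (1.30% to 2.65%). The difference of 0.804 percentage points had an interval that held 0 (-0.190 to 1.74). Random placements of the windows gave at most 25 and 16 overlaps. Within 1000 bp of a Sirt6 peak the numbers were 197 higher windows, or 8.88% (7.77% to 10.1%), and 48 lower windows, or 3.07% (2.33% to 4.05%), a difference of 5.81 percentage points (4.33 to 7.27). Random placements reached at most 51 and 35 windows at that distance. Untreated KO H3K56ac peaks overlapped 0 of the 2218 higher windows, which allows a share of up to 0.135%, and 19 of the 1562 lower windows (1.22%). Random placements gave a median of 1 and at most 7 overlaps for the higher windows, so the 0 is no sign of depletion. They gave at most 6 for the lower windows. Untreated KO H3K9ac peaks overlapped 6 higher and 22 lower windows, against at most 8 and 6 in random placements.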

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

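The predictions in this part were written after the results were seen, with exceptions. Those for input reads at regions called in all 8 lists, and for leaving those regions out, were written before. Leaving them out was itself an alternative added after the data were seen. The KO-only minus WT-only differences in Sirt6 share were planned, except with lists of equal length or without those regions.

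The genotype difference in H3K56ac went in opposite directions in the 2 conditions. KO had fewer H3K56ac peaks than WT in untreated cells (a difference of -515 peaks) and more after RA (176 peaks). The KO library held 0.742 of the WT filtered tags in untreated cells and 1.11 after RA. The share of the H3K56ac list at Sirt6 peaks was 14.6 percentage points higher in KO in untreated cells (12.4 to 16.8), and -0.294 points different after RA (-2.26 to 1.66). Neither difference between conditions was tested, with 1 library per group.

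Untreated KO acetylation regions at Sirt6 peaks set the untreated KO libraries of both marks apart from the other 6 acetylation libraries. With the stricter q limit this was weaker for H3K56ac. Its KO-only share at Sirt6 peaks (11.1%) was then above the WT-only share (1.09%) but not above that of shared regions (13.6%). Greater depth of the KO libraries is argued against, since the larger of the 2 ratios of KO to WT filtered tags was 0.935. Leaving out regions called in all 8 lists, with a smaller difference of 35.5 percentage points, decided nothing, since a region of 1 genotype is missing from a list by definition and only 11 of 5509 such regions were removed. Better enrichment in those libraries and an effect of Sirt6 loss in untreated cells cannot be told apart, because each group has 1 library: the untreated KO list led the next list of its mark by at least 14.045 percentage points for both antibodies, as either would give. The untreated WT libraries also had the shortest estimated fragments (155 bp for H3K9ac and 175 bp for H3K56ac). Whether fragment length contributes to the untreated difference between KO and WT was not tested. For an effect of Sirt6 loss in both conditions, a limit of 10 percentage points after RA was set after the results were seen. H3K56ac lay below it (-2.36, -6.95 to 2.01, and 4.42, 1.51 to 7.44, at the stricter q limit). The H3K9ac interval reached past it in the main setting (9.78, 7.01 to 12.2). It lay below at the stricter q limit (2.65, 0.506 to 4.66) and with lists of equal length (3.19, 0.800 to 5.76). At the stricter q limit even the untreated H3K56ac difference, 10.1 (7.20 to 13.6), did not clear that limit with its interval. Sirt6 peaks came from untreated cells only, so these values cannot decide the question.

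A set of 993 regions was called in all 8 acetylation lists, whatever the mark, genotype or condition. Sirt6 peaks overlapped 13.5% of them (11.5% to 15.8%), which does not settle whether they are sites of Sirt6 binding, since the WT Sirt6 library was shallower than every acetylation library and can miss peaks. Calling without a control library could produce such regions: CMS-IP windows at them had 3.28 times the median input RPKM of the other windows, above the ratio set beforehand. That rests on 5 windows, which ranged from 0.336 to 6.19 times the other windows' median, so it decides nothing here.

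In the CMS-IP windows lower in KO, the KO input held 0.547 of the WT reads after scaling to library size, so a loss of DNA copies in the KO cells or a gain in the WT cells may account for much of the lower IP signal. On chromosome 1 the input was lower also in the windows higher in KO (0.657), as a difference over the whole chromosome would give. On chromosome 14 it was not (1.14), which leaves parts of that chromosome. Chromosome 8 had the same pattern as chromosome 1, with input ratios of 0.738 in its lower and 0.781 (0.735 to 0.830) in its higher windows. The windows higher in KO had a summed input ratio of 1.00, which argues against more DNA as their cause as a set. The ratio differed between chromosomes, from 0.657 on chromosome 1 to 1.23 on chromosome 6, which held the most higher windows. KO input was higher by a factor of 1.5 in 16.5% of the higher windows and lower by that factor in 12.1%. More DNA therefore stays open for some of them. Chance alone would list at most about 1542 windows per direction, since windows with few reads cannot reach p under 0.001. The number of higher windows exceeded 1542 by 17.2 times its square root, which argues against counting noise alone. The lower windows numbered 1562, but that count does not make them noise. Of them, 33.2% lay on chromosome 14 and 20.7% on chromosome 1, and 65 had an adjusted p under 0.1 in the authors' deposited table. A difference in 5-hydroxymethylcytosine due to genotype, or between these single cultures, stays open for the higher windows and was not tested.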

How the results depend on the processing

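Lists of equal length for the Sirt6 shares, all alternatives for those shares in RA against untreated, the mean KO minus WT difference within mark and condition, leaving out regions called in all 8 lists, Benjamini-Hochberg adjustment, leaving out chromosomes 1 and 14, and the exact test of IP against input were chosen only after the results were seen. The other alternatives were not. Of 178 alternatives over 36 results, 102 kept the value, 68 moved it and 8 turned the direction of a value whose own interval had one. Among those moved, the RA H3K56ac difference in Sirt6 share, whose interval held 0, changed sign to 4.42 (1.51 to 7.44) at the stricter q. Of the 8, 4 are ratios from lists of equal length, near 1 by construction, which say nothing of direction. In the other 4, the whole interval lay past equality for untreated H3K9ac (0.615) and KO H3K9ac in RA against untreated (3.34), but not for WT H3K9ac in RA against untreated or for the CMS-IP split. Where no reason is given below, the cause was not tested. No paired test is reported, because the labels give no replicate numbers that pair libraries. Within mark and condition, the share of a list at Sirt6 peaks was higher in KO in 3 of 4 pairs, by a mean of 12.0 percentage points over the 4. Each group has 1 library, and neither the marks nor the conditions are replicates of each other, so no p-value is given. Positions relative to genes and gene lists, with their alternatives, were not run, as both need an mm9 annotation. What depth limits was not tested, since the lists hold no reads to thin.

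With a −log10 q of at least 10, the ratio of KO-only to WT-only regions was 0.358 for untreated H3K56ac, 0.615 for untreated H3K9ac (reversed), 1.24 for RA H3K56ac and 1.62 for RA H3K9ac. The difference in Sirt6 share between KO-only and WT-only regions was 10.1 and 21.8 percentage points for untreated H3K56ac and H3K9ac, and 4.42 and 2.65 after RA. The ratio of RA-only to untreated-only regions was 2.00 for KO H3K56ac, 1.06 for WT H3K9ac and 3.34 for KO H3K9ac, the last 2 turned past 1. Of the WT Sirt6 peaks, 6438 were left. The share of them overlapped by H3K9ac was 1.77% (WT) and 4.02% (KO) untreated and 2.25% and 2.501% after RA; for H3K56ac it was 2.53% and 3.03% untreated and 2.41% and 2.69% after RA.

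Lists of equal length give ratios near 1 by construction. They were 1.002, 1.02, 1.01 and 1.01 for KO against WT (untreated and RA H3K56ac, then untreated and RA H3K9ac), and 1.003 for RA against untreated in WT H3K56ac, 1.01 in WT H3K9ac and 1.002 in KO H3K9ac. The difference in Sirt6 share, which equal length does not fix, was 40.4 and 41.9 percentage points for untreated H3K56ac and H3K9ac, and -8.25 and 3.19 after RA. RA-only minus untreated-only, it was 10.6 in WT H3K56ac and -61.0 in KO H3K9ac, and with the stricter q -10.8 in KO H3K56ac and -34.7 in KO H3K9ac.

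On autosomes alone, the untreated H3K9ac ratio was 1.79, its difference in Sirt6 share 61.3 percentage points, and the RA-only to untreated-only ratio in KO H3K9ac 0.644. The share of Sirt6 peaks overlapped was 0.740% (WT untreated), 0.902% (WT RA) and 1.52% (KO RA) for H3K9ac, and 1.86%, 3.69%, 1.36% and 1.47% for H3K56ac in WT untreated, KO untreated, WT RA and KO RA. Counting acetylation peaks within 1000 bp, which can only add peaks, gave 12.9% for KO untreated and 2.24% for KO RA H3K9ac, and 2.80%, 5.31%, 2.01% and 2.09% for H3K56ac in the same order. Without regions called in all 8 lists, which can only remove overlaps, the shares were 0.110%, 8.37%, 0.331% and 0.965% for H3K9ac and 1.27%, 3.11%, 0.786% and 0.917% for H3K56ac, each in WT untreated, KO untreated, WT RA and KO RA.

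For CMS-IP, an adjusted p under 0.01 in the authors' deposited table left 86 windows, 48.8% of them higher in KO (38.6% to 59.2%). Benjamini-Hochberg adjustment gave 705 windows. The exact test gave 518 of the listed windows, of which 93.4% were higher, but it used the IP reads on which they were listed. It called simulated losses less often than simulated gains, but the losses also held fewer IP reads. Without chromosomes 1 and 14, 74.7% were higher. Within 1000 bp, the share of higher minus that of lower windows was 5.81 percentage points for Sirt6, -1.29 for WT untreated, -0.863 for WT RA and -1.48 for KO RA H3K9ac, and -1.27 for WT untreated, -1.91 for KO untreated and -0.825 for WT RA H3K56ac. Without chromosomes 1 and 14, the share of higher minus that of lower windows overlapped was -2.03 for KO untreated and -1.48 for KO RA H3K9ac, and -2.08 and -1.48 for H3K56ac.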

Other observations

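The values in this part were chosen after the results were seen, and no explanation of them was tested. Of 2703 regions called in a single acetylation list, 1247 overlapped a Sirt6 peak, and most of these came from the untreated KO lists. Sirt6 peaks overlapped 905 of the 1130 regions called only in KO untreated H3K9ac (80.1%, 77.7% to 82.3%) and 208 of the 313 called only in KO untreated H3K56ac (66.5%, 61.1% to 71.5%). They overlapped 0 of the 460 regions called only in WT untreated H3K9ac and 55 of the 212 called only in WT untreated H3K56ac (25.9%, 20.5% to 32.2%). After RA the H3K56ac order was the opposite, with 19 of 50 in WT (38.0%, 25.9% to 51.8%) and 20 of 111 in KO (18.0%, 12.0% to 26.2%). For H3K9ac after RA it was 0 of 129 in WT and 40 of 298 in KO (13.4%, 10.0% to 17.8%). Chromosome X held 1.76% of the Sirt6 peaks and 9.97% of the regions called in all 8 lists. Contigs without a place on a chromosome held 0.427% of the Sirt6 peaks and 6.55% of those regions.

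Of the windows with more 5-hydroxymethylcytosine signal in KO, 59 overlapped a Sirt6 peak and 197 lay within 1000 bp of one, against medians of 12 and 31 over random placements; 25.3% lay within 10000 bp. Of the windows lower in KO, 29 overlapped a peak and 48 lay within 1000 bp, against medians of 7 and 19, and 12.8% lay within 10000 bp. In the authors' deposited table the 73 higher windows of the densest 10 Mb stretch lay on chromosome 11 between 3269001 and 7745500; there the KO to WT ratio was 4.77 in the IP and 1.57 in the input (1.43 to 1.72). The input ratio was 1.23 (1.20 to 1.27) in the higher windows of chromosome 6.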
